A study of Mus musculus with 6 samples.

How the data were processed

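Total RNA of CD4+CD25+ T cells from 3 HDAC9-/- and 3 wild type samples was labelled with biotin and hybridised to Affymetrix expression arrays, 1 array per sample. RNA was purified on columns and amplified with a commercial kit, per the labels' protocols. The deposited table holds 1 log2 expression value per probe set and array, made by the authors with RMA per the submitters' processing notes. RMA is a method that, in its usual form, corrects background, normalizes the arrays to a common distribution and summarises the probes of each probe set. Its version and settings are not given in the sources used here. The values ran from 2.42 to 14.32, and the medians of the arrays, 5.69 to 5.81, were close but not identical. RMA pulls dim probe sets toward a common background, so fold changes of dim genes are understated. Groups and replicate numbers were taken from the sample titles. All columns of the table belonged to a sample of the series.

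The table has 22690 probe sets. The 64 control probe sets were left out, and 22626 were tested without any filter on brightness. Of these, 20380 carry 1 gene symbol in the platform annotation, 691 several and 1555 none, and only those with 1 symbol were named. Symbols were updated through the Entrez gene identifier for 20351 probe sets, with the mouse gene table of assembly GRCm38.p6, which also gave the order of neighbouring genes. The deposited table names no genome build, so no coordinates are given. List genes without a probe set of 1 symbol were left out of their lists.

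Differences are HDAC9-/- minus wild type on the log2 scale. They were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, genotype alone), with Benjamini-Hochberg adjustment and an adjusted p threshold of 0.05. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, on the probe set with the highest mean for each of 12393 genes. Adjustment was over 26 of the 27 lists, since the sex-linked list only checked the samples. Xist was bright and Y-linked genes were dim on all 6 arrays (the Eif2s3y probe set read 2.76 to 2.88), so the arrays did not differ in sex. The lists covered Treg and conventional T cell genes, effector Treg, naive and homing genes, chaperones, deacetylases and their partners, immediate early genes, metabolism, cell cycle, interferon response, helper T cell cytokines, interleukin-2 targets, apoptosis and ribosomal proteins. They also covered T cell identity, markers of B, plasma, myeloid, CD8 T and natural killer cells, of red cells and platelets and of pancreas, and the genes beside Hdac9. Within each list, adjusted p was also computed over the list alone. A list score is the mean over its genes of the value minus the gene's mean over the 6 arrays.

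The 27 lists, the tests of the comparison and the rule for named genes were fixed before the data were examined; the closing section says which further tests and lists were chosen later. The rule names Hdac9, list members with an adjusted p below 0.05, 2 to 4 examples per described list by smallest unadjusted p, and the 12 genes with the largest difference in each direction. A ranked gene needs an adjusted p below 0.05, groups that do not overlap and a mean in the higher genotype at or above the median of all probe sets. Free places were filled with genes at an unadjusted p below 0.01. Genes outside the rule that are named for comparison (Foxp3, Ctla4, Mki67, Tyms, Gata3, Tnf, Il21, Hspa1a and Hspa1b) were chosen after their values were seen. Markers of other cell types were included because magnetic separation does not remove all other cells.

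Alternatives tried were quantile normalization again, alignment of array medians, a filter that drops probe sets dimmer than the median, eBayes with trend and robust options, array weights, the replicate number as a block, and leaving out each array. Thresholds tried were an adjusted p of 0.10, an unadjusted p of 0.05, groups that do not overlap and 1 probe set per gene. For the lists they were camera with an estimated correlation, fry, and the mean of all probe sets per gene. Data were simulated for 22626 probe sets with the spread of these arrays. There limma called 36.4% of changed probe sets at a log2 change of 0.5, 78.5% at 1, 97.3% at 2 and 99.3% at 3. Of its calls, 5.29% were unchanged probe sets. The simulated data held many more changed probe sets than passed in the real data, which makes the adjusted threshold easier to reach. These shares may therefore be too high for the real arrays. Simulated on 12393 genes with independent noise, camera called a list shifted by 0.2 in 20 of 20 runs and made 2 calls of unshifted lists over all runs. Genes that vary together were not simulated, so this error rate may be too low for the real lists. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.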

Results

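Gene expression was measured in regulatory T cells (Treg), the CD4+ T cells that restrain other immune cells and depend on the transcription factor Foxp3. The cells were isolated with magnetic beads from mice as the CD4+CD25+ fraction, CD25 being the alpha chain of the interleukin-2 receptor. One group of 3 samples came from mice without HDAC9, a class IIa histone deacetylase, and the other group of 3 from wild type C57BL/6 mice. The series title asks how the deacetylases HDAC6, HDAC9 and sirtuin-1 control Foxp3+ Treg, and the comparison analysed here asks how the transcriptome of Treg from HDAC9-/- mice differs from that of wild type Treg. Each sample was hybridised to 1 array with 22690 probe sets, and the number of arrays limits the precision. The samples are described as independent, but whether each came from its own mouse is not given in the sources used here, so the p-values measure the spread between these samples. Pairs of arrays correlated at 0.990 to 0.997 across probe sets, which are not independent replicates. Wild type replicate 3 stood apart from the rest, with a mean correlation of 0.991 against 0.994 to 0.996 for the other arrays and a median log2 value of 5.69 against 5.77 to 5.81. The difference between the 3-prime and 5-prime control probe sets of Gapdh, a measure of RNA integrity and labelling, ran from 0.03 to 0.11 in wild type and from 0.15 to 0.28 in HDAC9-/- samples. The same difference for actin overlapped between the genotypes, at 0.33 to 0.46 in wild type and 0.42 to 0.60 in HDAC9-/- samples.

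The array carries 1 probe set for Hdac9 (1421306_a_at), and it was dim in every sample. Its log2 value was 3.50, 3.74 and 4.10 in wild type replicates 1 to 3 and 3.74, 3.62 and 3.66 in HDAC9-/- replicates 1 to 3, a difference of -0.10 with a standard error of 0.15 (limma, adjusted p = 0.839). The deleted exons are not given in the sources used here, so this probe set does not check the genotype labels. Foxp3 was bright in both genotypes, at 10.34 ± 0.05 in wild type and 10.37 ± 0.05 in HDAC9-/- Treg (SD, n = 3), and the 95% confidence interval of its difference ran from -0.13 to 0.19.

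HDAC9-/- Treg had more signal from the 1 probe set of Rab6b and less from 1 probe set each of Il7r and Ptp4a2. No other probe set passed the threshold. Rab6b, a small GTPase of the Golgi apparatus best known from neurons, rose from 4.26 ± 0.37 to 7.80 ± 0.06 (log2, SD, n = 3), which is 11.6-fold, with a difference of 3.54 and a standard error of 0.18 (limma, adjusted p = 0.00602). Its wild type signal lay below the median of all probe sets (5.76) and was not shown to be above background, so the fold may be understated. The rise rests on probe set 1434914_at, and no other probe set of Rab6b could check it. Il7r, the alpha chain of the interleukin-7 receptor and a gene that Treg carry at lower levels than conventional T cells, fell from 9.28 ± 0.01 to 7.94 ± 0.12 in probe set 1448576_at, a difference of -1.34 with a standard error of 0.08 (adjusted p = 0.00999). The brighter Il7r probe set 1448575_at read 11.32 ± 0.13 in wild type and 11.10 ± 0.08 in HDAC9-/- samples, and its difference of -0.22 did not pass. Ptp4a2, a tyrosine phosphatase, fell from 8.75 ± 0.09 to 7.52 ± 0.07 in probe set 1435129_at (difference -1.22, standard error 0.08, adjusted p = 0.0113), while its 3 other probe sets had differences of -0.06 to -0.56 that did not pass.

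**Figure D1:**
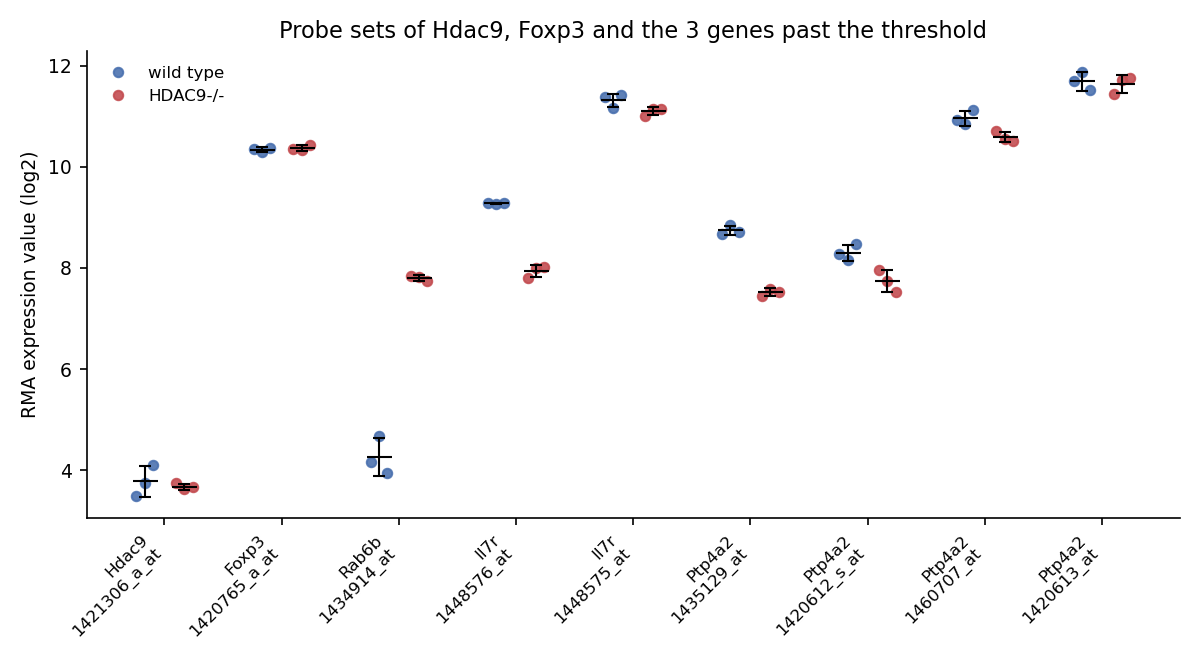
RMA expression values (log2, vertical axis) of each probe set of Hdac9, Foxp3, Rab6b, Il7r and Ptp4a2 on the 6 arrays, with wild type in blue and HDAC9-/- in red; points are single arrays, horizontal bars the means and whiskers 1 SD (n = 3). The HDAC9-/- arrays read 7.74 to 7.84 for Rab6b against 3.95 to 4.68 in wild type, and the Il7r and Ptp4a2 probe sets of each gene differ in how far the genotypes lie apart.

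Across the array, 3 of 22626 probe sets passed (1 higher and 2 lower), and 1987 had an unadjusted p below 0.05, of which 1256 were higher and 731 lower in HDAC9-/- Treg; an even spread of p-values gives 1131.3, and 1 split of the arrays that mixed the genotypes reached 1777. The genotypes did not overlap for 3856 probe sets, 17.0% of those tested, where chance gives 10%. With a variance prior that follows brightness and is robust to outliers the count was 15, with array weights 6, with 1 probe set per gene 1 and with the replicate number as a block 0. It fell to 0 without wild type replicate 1 or without any 1 of the HDAC9-/- replicates, was 1 (Rab6b) without wild type replicate 2 and 6 without wild type replicate 3. Single arrays of the called probe sets read 3.95 to 4.68 in wild type and 7.74 to 7.84 in HDAC9-/- samples for Rab6b. They read 9.27 to 9.28 and 7.80 to 8.02 for Il7r, and 8.67 to 8.85 and 7.44 to 7.59 for Ptp4a2. No left-out array could thus bring these groups together, although calls were lost.

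The other genes named by the rule set beforehand did not pass. That rule required groups that do not overlap. Chil3, a chitinase-like protein of macrophages and neutrophils, read 7.35 ± 0.66 in wild type and 8.80 ± 0.11 in HDAC9-/- samples (SD, n = 3, difference 1.46, adjusted p = 0.398). Ltf, which encodes lactoferrin, had a difference of 1.22. S100a9, a calcium-binding protein of neutrophils and monocytes, had 1.01 (0.66 without wild type replicate 1), Fpr2, a formyl peptide receptor, 0.93, and Hp, which encodes haptoglobin, 0.89. Wild type replicate 1 was also the lowest wild type array for Chil3 (6.61), Ltf (6.50), Fpr2 (4.90) and Hp (5.37). Without it the differences of Chil3, Fpr2 and Hp were 1.09, 0.78 and 0.76. The score of the myeloid marker list was 0.21 ± 0.28 in HDAC9-/- and -0.21 ± 0.22 in wild type samples. Both probe sets of Egln3, a prolyl hydroxylase that acts on hypoxia-inducible factor, were higher, by 1.05 and 1.15 (adjusted p = 0.240 for the first). Pik3cg, the catalytic subunit of a phosphoinositide 3-kinase of leukocytes, had differences of 1.18 and 0.08 in its 2 probe sets. D13Ertd608e (1.26), Ifitm6 (1.09), Ncmap (0.95) and Wfdc21 (0.94) complete the group. Ifitm6 and Wfdc21 also had their lowest wild type value in replicate 1 (6.13 and 4.91).

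Among the genes that were lower without passing, Il4, the T helper 2 cytokine, read 5.86 ± 0.16 in wild type and 5.06 ± 0.06 in HDAC9-/- Treg (SD, n = 3, difference -0.80, adjusted p = 0.202). Cxcr6, a chemokine receptor of activated T cells, was lower in both probe sets, by -0.78 and -0.80, and so was the tetraspanin gene Tspan13, by -0.71 and -0.65 (adjusted p = 0.115 for the first). Tspan13 passed with the trended and robust prior (adjusted p = 0.00214) and with array weights (adjusted p = 0.0340), and Egln3 passed with that prior (adjusted p = 0.0255). Smarcc1, a subunit of the BAF chromatin remodeller, differed by -0.85 in 1 probe set and by less than 0.01 in the brighter one, which read 8.87 in both genotypes. The adenylyl cyclase gene Adcy6, with 1 probe set, differed by -0.69. The pro-apoptotic gene Bik differed by -0.59, with -0.92 and -0.32 in its other probe sets. The interferon regulatory factor gene Irf3 and the RNA-binding protein gene Hnrnpr differed by -0.69 and -0.65 in 1 probe set each. The differences in their brightest probe sets were -0.065 and -0.036. Crk, an adaptor protein gene (-0.80), and Ctr9, a subunit of the PAF1 transcription complex (-0.58), had other probe sets of opposite sign.

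Of the gene lists fixed before the data were examined, those of cell cycle genes, myeloid markers and respiratory chain genes were higher in HDAC9-/- Treg. S and G2/M phase genes had positive differences for 26 of 27 measured members, with a median of 0.22 (limma camera, adjusted p = 3.65e-10; adjusted p = 0.493 with an estimated correlation). No member passed over all genes, and 3 passed adjusted over the list alone. These were Aurka, a mitotic kinase, at 6.45 ± 0.01 in wild type and 6.80 ± 0.05 in HDAC9-/- (SD, n = 3), Birc5, a subunit of the chromosomal passenger complex, at 7.77 ± 0.06 and 8.14 ± 0.09, and Bub1, a spindle checkpoint kinase, at 6.89 ± 0.10 and 7.31 ± 0.09 (adjusted p = 0.0168 each). Mki67, the proliferation marker, differed by 0.31 with a standard error of 0.10, and Tyms was the 1 member with a negative difference. Respiratory chain and ATP synthase genes had positive differences for 22 of 27 members and a median of 0.097 (camera, adjusted p = 0.00179; adjusted p = 0.493 with an estimated correlation), with 0 members passing over all genes and 0 adjusted over the list alone. Ndufb8 (0.15), Sdhd (0.14) and Atp5o (0.14) had the smallest p-values, and the genotypes did not overlap for 17 of the 27 genes, all higher in HDAC9-/- samples. The directional fry test passed for the respiratory chain list (adjusted p = 0.0218) and not for the other lists called by camera. Its adjusted p was 0.115 for the cell cycle and helper T cell lists, 0.138 for the unfolded protein response and 0.226 for the myeloid, plasma cell and interleukin-2 lists. In both groups of genes the HDAC9-/- samples had, on average, the higher myeloid score, which was 0.41, 0.34 and -0.11 in HDAC9-/- replicates 1 to 3 and -0.47, -0.10 and -0.07 in wild type replicates 1 to 3, and the wider Gapdh 3-prime to 5-prime difference, while the actin difference overlapped.

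Myeloid markers had positive differences for all 15 measured genes, with a median of 0.36 (camera, adjusted p = 1.87e-05; adjusted p = 0.493 with an estimated correlation). None passed over all genes or adjusted over the list alone. The calprotectin genes S100a9 and S100a8 differed by 1.01 and 0.96. Flt3, a receptor of dendritic cells and progenitors, differed by 0.47, and Cst3, which encodes cystatin C, by 0.33. Markers of CD8 T cells and natural killer cells had a median of 0.26 and did not pass (adjusted p = 0.0613), with the smallest unadjusted p for Eomes (0.24) and Ccl5 (0.30). They passed without wild type replicate 3, without HDAC9-/- replicate 3, with array weights, with the trended and robust prior and with the mean of all probe sets per gene.

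**Figure D2:**
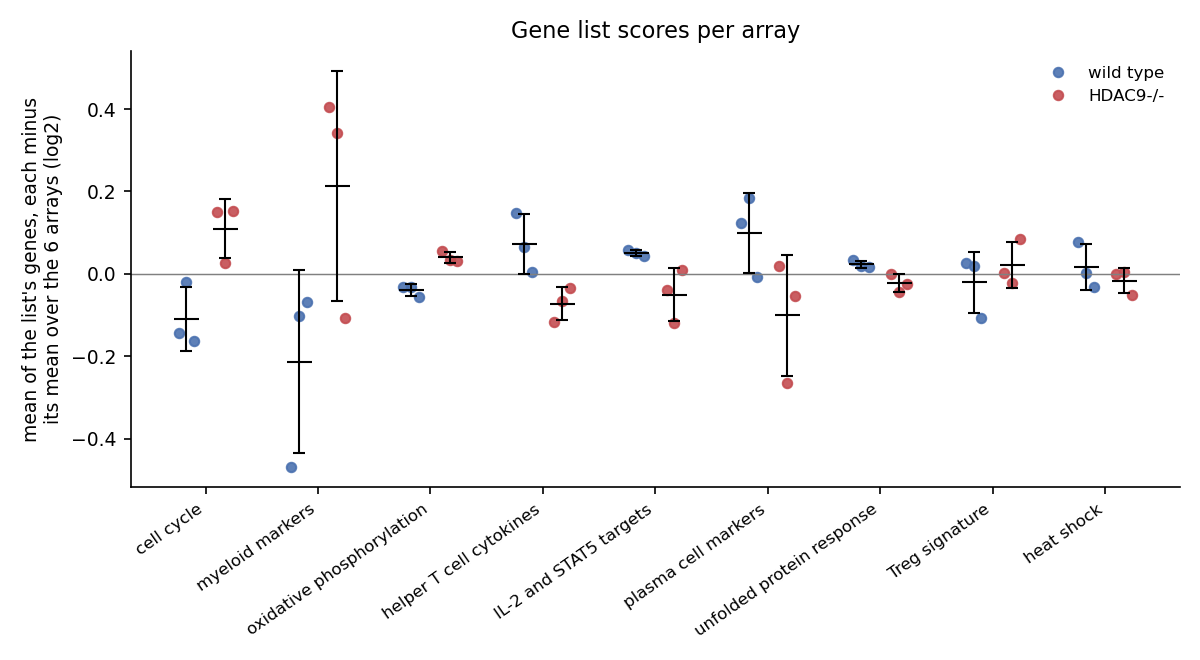
Scores of the 7 lists that passed and of the Treg signature and heat shock lists on each array; the score (vertical axis, log2) is the mean over a list's genes of the value minus the gene's mean over the 6 arrays, with wild type in blue, HDAC9-/- in red, horizontal bars for means and whiskers for 1 SD (n = 3). Cell cycle scores do not overlap between genotypes, while the myeloid score of HDAC9-/- replicate 3 (-0.11) lies within the wild type range of -0.47 to -0.07.

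The helper T cell list was lower in HDAC9-/- samples, and Il4, Tbx21 and Il12rb2 were the members that passed within it. The list had negative differences for 11 of 17 measured genes and a median of -0.12 (camera, adjusted p = 0.00303; adjusted p = 0.493 with an estimated correlation). No gene passed over all genes, and 3 fell adjusted over the list alone: Il4, Tbx21 and Il12rb2. Tbx21, which encodes the T helper 1 factor T-bet, read 8.29 ± 0.19 in wild type and 7.76 ± 0.07 in HDAC9-/- Treg (SD, n = 3, adjusted p = 0.0151 over the list), and Il12rb2, a chain of the interleukin-12 receptor, 4.81 ± 0.17 and 4.39 ± 0.06 (adjusted p = 0.0266 over the list). Both Il12rb2 means lay below the median of all probe sets (5.76). Il4 had an adjusted p of 0.00136 over the list. Ifng (-0.56) and Cxcr3 (-0.31), 2 genes that T-bet activates, were lower without passing, Il21 (0.45) was higher without passing, and Gata3 (-0.16) and Tnf (0.04) differed little. The median was -0.078 without wild type replicate 1 or without HDAC9-/- replicate 1, and the list still passed. CD8 T cells and natural killer cells also express Tbx21 and Ifng, and the median of their marker list had the opposite sign (0.26). Whether Treg or other cells of the isolated fraction carried the lower signal was not tested. The samples with the lower helper T cell score, -0.07 ± 0.04 in HDAC9-/- against 0.07 ± 0.07 in wild type, were those with the wider Gapdh 3-prime to 5-prime difference and, on average, the higher myeloid score (0.21 against -0.21).

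**Figure D3:**
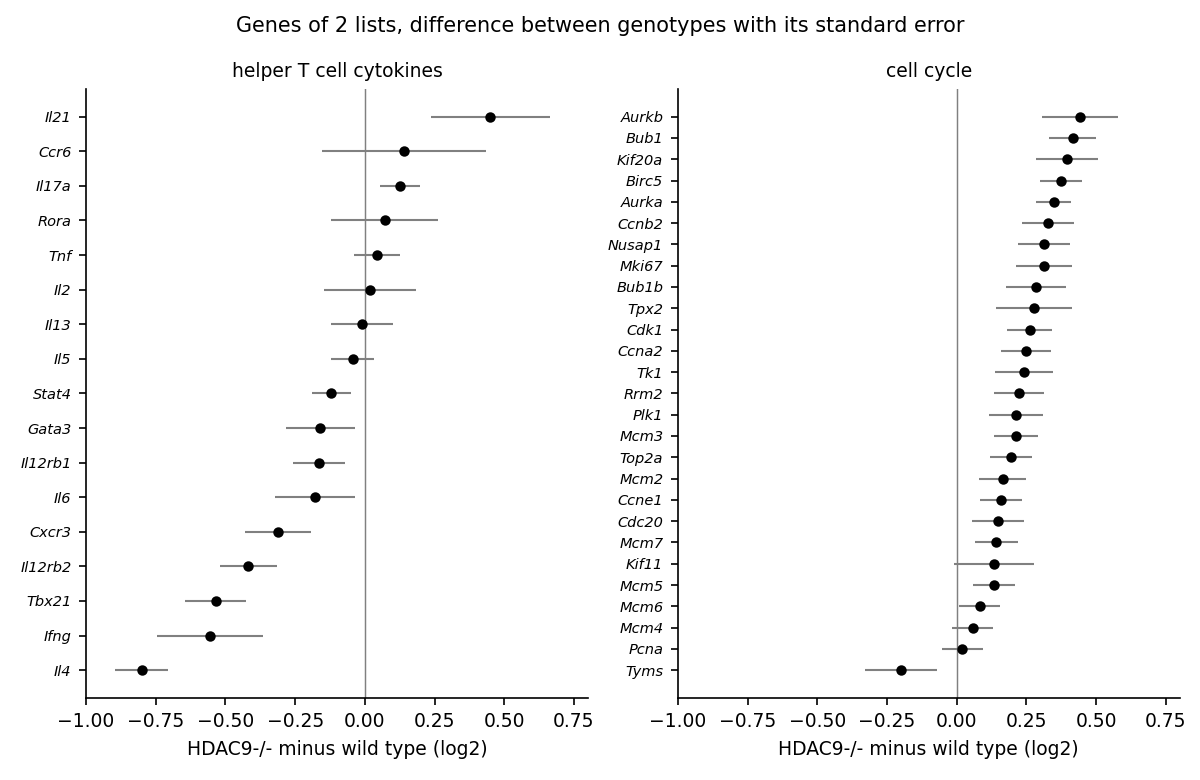
Difference between genotypes (HDAC9-/- minus wild type, log2, horizontal axis) of each measured gene of the helper T cell list (left) and the cell cycle list (right), with points for the estimates and bars for 1 standard error (3 arrays per genotype). Il4 (-0.80), Ifng (-0.56) and Tbx21 (-0.54) lie lowest on the left, and on the right 26 of 27 genes lie above 0.

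Targets of interleukin-2 signalling through STAT5 were lower as a list, with negative differences for 8 of 11 genes and a median of -0.091 (camera, adjusted p = 0.0103; adjusted p = 0.493 with an estimated correlation). No member passed over all genes or adjusted over the list alone. Socs1, a feedback inhibitor of cytokine signalling, differed by -0.34, Socs2 by -0.22, the lymphotoxin gene Lta by -0.17 and the receptor chain Il2rb by -0.18. Genes of the unfolded protein response had negative differences for 13 of 19 members and a median of -0.057 (adjusted p = 0.0466; adjusted p = 0.493 with an estimated correlation), with no member passing either way. The endoplasmic reticulum chaperone gene Hsp90b1 (-0.31) and the transcription factor gene Xbp1 (-0.18), both prominent in secretory cells, had the smallest p-values. Plasma cell markers had negative differences for all 4 measured genes and a median of -0.16 (adjusted p = 0.0466; adjusted p = 0.493 with an estimated correlation). Of these, 0 passed over all genes and 1 adjusted over the list alone, Jchain, the joining chain of secreted antibodies, at 11.99 ± 0.06 in wild type and 11.52 ± 0.11 in HDAC9-/- samples (adjusted p = 0.00305 over the list). The median of the unfolded protein response list was -0.032 and -0.023 without wild type replicates 1 and 3 and -0.031 without HDAC9-/- replicate 1. Its call ended without any 1 of the wild type replicates or without HDAC9-/- replicate 2, with quantile normalization again, with array medians aligned and with the replicate block. The plasma cell median was -0.26 without wild type replicate 3 and -0.25 and -0.074 without HDAC9-/- replicates 1 and 2. Its call ended without wild type replicate 1 or 2, without HDAC9-/- replicate 2 and with array medians aligned, and the interleukin-2 call ended without HDAC9-/- replicate 2. The interleukin-2 median was -0.057 without wild type replicate 3. The HDAC9-/- group, in which these lists were lower on average, had the higher mean myeloid score (0.21 against -0.21) and the wider Gapdh difference. The interleukin-2 and unfolded protein response scores did not overlap between genotypes, as the Gapdh difference did not, while the plasma cell scores and the myeloid scores did overlap.

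No shift of the Treg signature genes was detected. Of 29 measured signature genes 17 had positive and 12 negative differences, with a median of 0.024 (camera, adjusted p = 0.995). The median turned to -0.0014 when array medians were aligned, and 0 members passed over all genes or adjusted over the list alone. Ctla4, an inhibitory receptor, read 11.20 ± 0.03 in wild type and 11.30 ± 0.17 in HDAC9-/- Treg, and Ecm1 (-0.29) and Socs2 (-0.22) had the smallest p-values. Heat shock genes, the chaperones that assist protein folding, had a median of -0.064 with negative differences for 15 of 22 members (adjusted p = 0.332) and no member past either threshold. The co-chaperone gene Bag3 was higher by 0.41 and Hsp90aa1 lower by -0.18, neither passing, while the means of Hspa1a and Hspa1b were 3.18 to 4.08, near the bottom of the array's range. The other deacetylases had a median of -0.0085 over 12 genes (camera, adjusted p = 0.754), and none passed either threshold. That median turned to 0.018 with dim probe sets left out. Hdac1 was lower by -0.31 and Hdac6 and Sirt3 higher by 0.21 and 0.18.

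Of the genes beside Hdac9 on its chromosome, Tspan13 was lower and Pik3cg higher in HDAC9-/- Treg, judged within their list by the brightest probe set of each gene. The other Pik3cg probe set differed by 0.08 and the other Tspan13 probe set by -0.71. Over all genes 0 of the 17 measured members passed, and adjusted over the list alone 1 was higher and 1 lower. These were Pik3cg, at 7.01 ± 0.38 in wild type and 8.19 ± 0.14 in HDAC9-/- samples (adjusted p = 0.00366 over the list), and Tspan13, at 10.86 ± 0.04 and 10.21 ± 0.14 (SD, n = 3; adjusted p = 0.00271 over the list). Ahr, the aryl hydrocarbon receptor gene, was higher by 0.40 and Bzw2 lower by -0.26, without passing. The list, with a median of -0.00058, was not called in one direction (camera, adjusted p = 0.846), while the test for change in either direction gave an adjusted p of 0.00146 (limma fry). That test also passed for apoptosis genes at 0.00146, for interferon response and glycolysis genes at 0.00178, and for the oxidative phosphorylation, fatty acid oxidation, interleukin-2, helper T cell, cell cycle and deacetylase lists at 0.00271 to 0.0227.

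**Figure D4:**
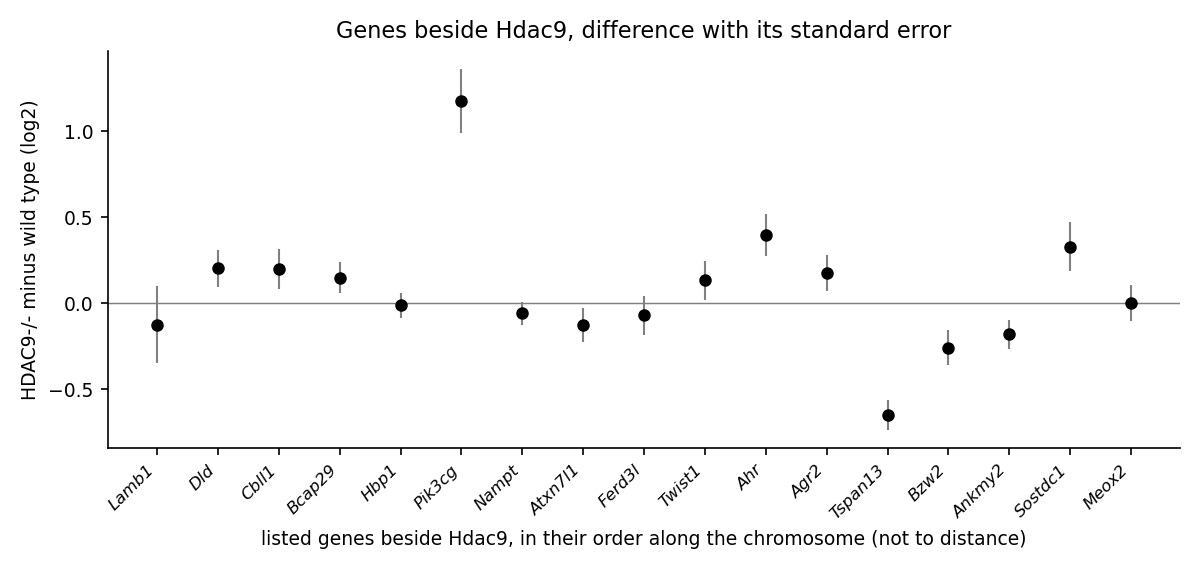
Difference between genotypes (HDAC9-/- minus wild type, log2, vertical axis) of the 17 measured genes of the list beside Hdac9, in their order along the chromosome, with 6 measured genes between them left out and not spaced by distance (horizontal axis); points are estimates and bars 1 standard error. Pik3cg (1.18, with 0.08 in its other probe set) lies highest and Tspan13 (-0.65) lowest.

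The remaining lists did not pass in the directional test, and none of their members passed over all genes. Immediate early genes had a median of -0.075 (camera, adjusted p = 0.0735), fatty acid oxidation genes 0.054 (adjusted p = 0.0924) and glycolysis genes 0.10 (adjusted p = 0.304). The immediate early list passed with fry (adjusted p = 0.0153), with dim probe sets left out and with the trended and robust prior. The fatty acid oxidation list passed with that prior and without HDAC9-/- replicate 2, both lists passed with the mean of all probe sets per gene, and the naive and homing list passed with that mean alone (median -0.084, adjusted p = 0.0463). Medians and adjusted p were 0.0093 and 0.376 for conventional T cell genes, 0.012 and 0.528 for naive and homing genes, 0.015 and 0.752 for effector Treg genes, and 0.017 and 0.937 for ribosomal proteins. These 4 medians were negative with array medians aligned, and those of the conventional T cell and effector Treg lists also with quantile normalization again. They were 0.052 and 0.702 for partners of class IIa deacetylases, 0.027 and 0.754 for apoptosis genes, -0.036 and 0.304 for T cell identity genes, 0.046 and 0.618 for B cell markers, and -0.082 and 0.332 for erythroid and platelet markers. Among the B cell markers Ighm, an immunoglobulin heavy chain gene, read 13.78 in wild type and 13.56 in HDAC9-/- samples in its brightest probe set. Foxp3 read 10.34 and 10.37. Cells other than Treg may thus have contributed signal in both genotypes. Pancreas markers had a median of -0.040 (adjusted p = 0.376), and adjusted over the list alone 1 was higher (Cela1, a pancreatic elastase gene, 0.60) and 1 lower (Cpb1, a carboxypeptidase gene, -0.33). Cela1 read 5.41 in wild type and 6.01 in HDAC9-/- samples. Cpb1 read 3.49 and 3.15, near the bottom of the array's range. Interferon response genes had a median of -0.0018 (adjusted p = 0.402), and adjusted over the list alone 1 was higher (Mx1, an antiviral GTPase gene, 0.47) and 1 lower (Usp18, a brake on interferon signalling, -0.32). No other of these lists had a member that passed adjusted over the list alone. The camera statistic pointed down while median and mean were above 0 for the Treg signature, apoptosis and B cell lists. For the conventional T cell and naive and homing lists the median was above 0 and the mean and the test below, and for the genes beside Hdac9 the median was below 0 and the mean and the test above.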

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

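Of the alternatives, leaving dim members out of the lists was chosen after seeing the data. Signal over background limits dim genes: without probe sets dimmer than the median Hdac9 has no value. The 3 probe sets, and the same 3 genes, passed with quantile normalization again, with array medians aligned and with dim probe sets left out. Their number was 15 with the trended and robust prior, 6 with array weights, 0 with the replicate block, 5 at an adjusted p below 0.10, 1 with 1 probe set per gene, 1987 at an unadjusted p below 0.05 and 3856 where groups do not overlap (chance gives 10%). Without 1 array it ran from 0 to 6. Fewer arrays, a looser threshold, fewer probe sets tested or no adjustment are part of some of these settings. With 1 probe set per gene the brightest was kept, which dropped the called Il7r and Ptp4a2 probe sets. For the rest the cause was not tested. Samples of the 2 genotypes share only a number: residuals of same-number samples correlated at 0.036, 0.099 and -0.249. The 24 genes named for their size kept direction and side of the threshold in 262 comparisons, lost the call in 17 and gained it in 3, and none reversed. The rule required groups that do not overlap, so leaving out an array could not reverse a direction. Only Rab6b, Il7r and Ptp4a2 had passed, so all 17 lost calls were theirs. For the other named genes, keeping the side of the threshold meant not passing again. The number of lists was 0 with an estimated correlation, 2 with fry and 11 with the mean of all probe sets per gene; the cause was not tested. The cell cycle, myeloid, oxidative phosphorylation and helper T cell lists kept their calls with each left-out array and each other setting that used camera's preset correlation. The Hdac9 difference was 0.00037 with array weights and -0.24 to 0.054 without 1 array, and none of these passed.

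The lists whose medians reversed had not passed, and under these settings only the naive and homing list passed (mean of all probe sets); the cause was not tested. With array medians aligned the medians were -0.0014 for the Treg signature, -0.0089 for ribosomal proteins, -0.011 for effector Treg, -0.014 for naive and homing and -0.016 for conventional T cell genes. With quantile normalization again they were -0.0020 for conventional T cell and -0.0072 for effector Treg genes. With array weights they were -0.0067 for the Treg signature, -0.050 for conventional T cell, -0.091 for naive and homing genes, 0.011 for deacetylases, 0.042 for erythroid and platelet markers and 0.070 for the genes beside Hdac9. Deacetylases had 0.018 with dim probe sets left out and 0.018 with bright members only. With the mean of all probe sets per gene they were -0.0060 for ribosomal proteins, -0.045 for conventional T cell genes, -0.067 for class IIa partners, -0.075 for apoptosis, -0.084 for naive and homing genes, 0.0027 for deacetylases and 0.012 for the genes beside Hdac9. Without 1 array the medians ran from -0.055 to 0.17 for B cell markers, -0.033 to 0.073 for the genes beside Hdac9, -0.042 to 0.050 for the Treg signature, -0.0086 to 0.040 for apoptosis and -0.080 to 0.019 for conventional T cell genes. They ran from -0.029 to 0.017 for deacetylases, -0.026 to 0.092 for effector Treg genes, -0.11 to 0.039 for erythroid and platelet markers, -0.062 to 0.024 for interferon response, -0.20 to 0.035 for naive and homing genes and -0.14 to 0.10 for pancreas markers.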

Other observations

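The tests of the Il7r and Ptp4a2 probe sets, of the genes beside Hdac9 and of the cell cycle score against the myeloid score were chosen after the results were seen. The hypoxia and MHC class II lists were added after the Egln3 and myeloid differences were seen and before the lists themselves were tested. At an adjusted p below 0.10, 2 further probe sets passed, both below the median brightness of 5.76 in each genotype. Prm1, the gene of the sperm protein protamine 1, read 3.12 ± 0.07 in wild type and 4.17 ± 0.17 in HDAC9-/- Treg in probe set 1437054_x_at, and Zfp991, a zinc finger gene, read 5.63 ± 0.18 and 3.96 ± 0.29 in probe set 1451477_at (SD, n = 3). The other Prm1 probe sets differed by 0.03 and 1.43 and the other Zfp991 probe set by 0.54, the opposite sign, and none of these passed. Cap1, an actin-binding protein gene chosen after its values were seen, read 11.04, 10.99 and 9.33 in wild type replicates 1 to 3 and 9.81, 9.94 and 9.81 in HDAC9-/- replicates 1 to 3 (probe set 1417461_at). Fscn1, an actin-bundling protein gene chosen the same way, read 8.67 ± 0.85 in wild type and 9.71 ± 0.32 in HDAC9-/- samples (SD, n = 3, probe set 1416514_a_at), with wild type replicate 3 at 9.63, and its other probe sets differed by 0.61, 0.16 and -0.04; none passed.

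The fall of 1 Il7r and 1 Ptp4a2 probe set was set against a lower level of the whole transcript in HDAC9-/- cells, which would lower a gene's probe sets alike. The difference between the called and the brighter Il7r probe set changed by -1.12 with a standard error of 0.075, and that between the called and the brightest Ptp4a2 probe set by -1.17 with a standard error of 0.10, which argues against it as the whole cause for either gene. A change in transcript ends or splicing, or a sequence variant under the probes, may lie behind it, and neither was tested.

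Donor-strain sequence left around the targeted locus may lie behind the differences among the genes beside Hdac9. The mean absolute moderated t of the list was 2.10, at percentile 99.4 of 12039 runs of as many adjacent measured genes (median 1.09), but the list leaves out 6 measured genes within its span. All 23 genes of the span had a mean of 1.85, at percentile 99.04 of 11919 runs. Without Tspan13 and Pik3cg the list lay at percentile 91.6 and the span at 90.1. These 2 genes were taken out for their large differences while the compared runs kept all their genes, so part of the fall was built in. An effect of the deletion on regulation in the region would look alike and stays open.

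The higher cell cycle genes could come from the normalization of probe sets of their brightness, from carried-over myeloid cells or from more cycling Treg. The list's median lay at percentile 100 of 10000 random lists matched on brightness, which argues against the first. Within genotype the cell cycle score had a slope of -0.023 on the myeloid score (standard error 0.17, 95% confidence interval -0.57 to 0.52). The interval holds the slope of 0.51 that would carry the whole difference, so carried-over cells cannot be told apart from the genotype with 6 arrays. At equal myeloid score the genotypes differed by 0.23 with a standard error of 0.10. That score averages genes that did not move alike. In HDAC9-/- replicate 3, which scored -0.11, S100a9 read 11.70, against 9.94 to 10.99 in wild type. Equal score may therefore not mean equal carry-over of each myeloid cell type, and the comparison cannot settle the source. More cycling of HDAC9-/- Treg stays open as an untested biological explanation.

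A broader rise of hypoxia-inducible genes was tested as a hypothesis for the higher Egln3. Egln3 lies on the same chromosome as Hdac9 but is not in the list of genes beside it. Whether donor-strain sequence reaches Egln3 was not tested. The hypoxia list without Egln3 had a median of 0.050 with 11 of 18 genes positive (limma camera, adjusted p = 0.213 over both added lists). A p at or above 0.05 with a median below 0.1 had been set beforehand to count against the hypothesis, and these values met that criterion. By that criterion the result counts against a broad rise of these genes. The criterion did not weigh the members' spread, so a small rise stays open. If the higher myeloid markers came from more antigen-presenting cells of every kind, MHC class II genes could be higher too. They had a median of 0.23 with 7 of 8 genes positive (camera, unadjusted p = 0.0328, the value the test was set on, and adjusted p = 0.0655 over both added lists; p = 0.390 with an estimated correlation). Cd74 (11.11 ± 0.25 in wild type, 11.20 ± 0.27 in HDAC9-/-) and H2-Aa (10.10 ± 0.26 and 10.33 ± 0.32) had the brightest probe sets (SD, n = 3), which compares signals and not transcript levels, and H2-Oa (0.30) and H2-DMa (0.28) the largest differences. Separation on CD4 and CD25 would remove most such cells, and B cells carry these genes as well. The B cell marker list did not pass, with a median of 0.046 and 6 of 11 genes positive (camera, adjusted p = 0.618).

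The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. As many probe sets passed in 1 of the 10, the real one, with 3 against a highest other count of 0. As many lists passed in 2 of the 10, with 7 in the real split and 7 in the split that joined wild type replicates 1 and 2 with HDAC9-/- replicate 3. The probe sets at an unadjusted p below 0.05 numbered 1987 in the real split, 1777 in that split and 1458 in the split that joined wild type replicates 1 and 3 with HDAC9-/- replicate 1.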
